A study of Arabidopsis thaliana with 6 samples.

How the data were processed

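RNA from 9-day-old Arabidopsis thaliana seedlings was measured on 6 Affymetrix ATH1 arrays in 3 groups of 2, each array from a separate liquid culture per the labels' design text. The groups were GR-bdl seedlings given auxin (IAA) alone, GR-bdl seedlings given dexamethasone (DEX) and then IAA, and mp seedlings given DEX and then IAA. The deposited values are gcRMA intensity values, 1 column per array; the tool name comes from the submitters' processing notes, and its version is not given in the sources used here. gcRMA corrects the background by probe sequence, normalizes arrays to a common distribution and summarises the probes of a probe set. The scale is linear, as the values show: all lay above 0, and the array medians lay between 26.1 and 27.1. The group of each array was taken from its source label and the design text, because the treatment text of the labels names DEX for every sample and the mp titles leave it out. Their replicate numbers name the arrays and did not enter the fit.

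The log2 of each intensity was taken with no pseudocount and no filter. The 64 control probe sets were left out, which left 22746 probe sets. Of these, 13513 (59.4%) were paired with 1 gene in the annotation used here, 503 with several and 8730 with none. Of the first kind, 13436 matched a locus in the RefSeq table (assembly TAIR10.1), which was used for names only, so no coordinates are given. They name 13355 distinct genes. A probe set with several genes or none was counted but not named.

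Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit with a mean per group, then eBayes), with all 6 arrays in 1 fit. The fit had 3 residual degrees of freedom and 5.12 prior degrees of freedom, with a prior SD of 0.13 on the log2 scale. Benjamini-Hochberg adjustment ran over all probe sets of a comparison, with a threshold of 0.05, and a call below means a limma adjusted p under it. The 3 comparisons were GR-bdl with against without DEX, mp against GR-bdl without DEX, and mp against GR-bdl with DEX. Errors of differences are limma standard errors (SE), and levels are means ± SD of 2 arrays. The number of arrays limits the precision. Tested on simulated data with the size of the DEX comparison, the fit recovered 25% of changes of 0.5, 97.5% of changes of 1 and 100% of changes of 2 on the log2 scale, with 9 false calls. The simulated noise was normal, with the variances from eBayes and the same spread in every group. Recovery in the real data may be lower.

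The rule for named genes, the 20 gene lists and the alternatives were fixed before the data were examined. Named were the 8 largest increases and decreases of each comparison among calls with 1 gene and arrays that did not overlap between groups, a separation that chance gives in 33.3% of cases for 2 against 2. Up to 4 called members of each list were added, by smallest p, with the 8 lowest and 8 highest mean changes of the overlap. MP, BDL, TMO3, TMO5, TMO6, TMO7 and ATHB8 were to be named always, with a further gene that is not reported here. Genes that only repeated a group could be left out. A group mean under 4 was called near the low end of the gcRMA range, which held 43.1 to 44.1% of the probe sets of an array. Probe sets marked as matching several transcripts are given as uncertain between copies.

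Of the 352 genes on the 20 lists, 48 had a probe set paired with them, and 3 lists with at least 5 measured genes were tested. Measured were 7 of 27 listed Aux/IAA genes, 5 of 8 GH3 genes, 7 of 34 other early auxin genes and 1 of 25 SAUR genes. These lists need not hold every member of a family, and no other gene was assigned to them. A further 34 lists and gene families were written after the annotation had been seen and before any difference had been. List tests used camera with a preset correlation of 0.01, which compares a list with all other genes, then camera with an estimated correlation, and fry. The form with an estimated correlation rests on the 3 residual degrees of freedom, and a list can fail it for that reason alone. The p of fry tests whether the genes of a list move, on balance, in 1 direction, and does not compare them with other genes. A gene with several probe sets was represented by the probe set with the highest mean.

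Overlap between comparisons that share control arrays was set against 100 simulated sets of unchanged groups and against independent lists. Other settings tried were a repeated quantile normalization, centring on array medians, a filter on low means, a size minimum, the replicate block, leaving out each array, other settings of eBayes, the 4 arrays compared alone, and other list tests. Centring on the hybridization controls, 18 probe sets of RNA added before hybridization, was chosen after seeing the data, as was the overlap of lists matched on mean level. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.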

Results

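Transcript levels were measured in 9-day-old seedlings of 2 Arabidopsis lines. The GR-bdl line carries a stabilised form of BODENLOS (BDL), an Aux/IAA repressor of auxin response, fused to the glucocorticoid receptor and driven by the RPS5A promoter. Such a fusion enters the nucleus when the synthetic glucocorticoid dexamethasone (DEX) is given. The other line, mp-B4149, is mutant for MONOPTEROS (MP), an auxin response factor that BDL binds, and mp seedlings are known for failing to form an embryonic root. Both mp cultures and 2 of the 4 GR-bdl cultures received 10 µM DEX for 1 h, and all 6 then received 50 µM of the auxin IAA for 1 h. The other 2 GR-bdl cultures are the controls. Median intensities of the 6 arrays lay between 26.1 and 27.1. The median SD between the arrays of a group was 0.07 (controls), 0.11 (GR-bdl with DEX) and 0.10 (mp) on the log2 scale. No probe set was paired with MP, BDL, TMO3, TMO5, TMO6, TMO7 or ATHB8 in the annotation used here, so these genes were not analysed here and the labels were not checked on them.

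The first comparison asked which transcripts changed when GR-bdl was released before auxin. Several genes of early auxin response were lower in GR-bdl seedlings given DEX than in the controls. SAUR10, a small auxin up RNA gene, fell by 4.54 ± 0.15 (SE) on the log2 scale, from 7.22 ± 0.23 to 2.68 ± 0.04 (SD, n = 2), with a limma adjusted p of 5.4e-06. IAA29, an Aux/IAA repressor gene, fell by 4.24 ± 0.15, from 9.20 ± 0.02 to 4.96 ± 0.02, with the same limma adjusted p. GH3.1, GH3.5 and GH3.3, whose enzymes join auxin to amino acids, fell by 2.67 ± 0.13, 2.42 ± 0.30 and 2.12 ± 0.11. SAUR10 and GH3.1 ended near the low end of the gcRMA range.

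The 3 preset lists with enough genes were all lower after DEX. Of the 7 measured Aux/IAA genes, 2 fell, IAA29 and IAA30 (−1.90 ± 0.12), and 5 were not called. Adjusted over the list alone, 4 fell. IAA30 ended near the low end of the range. Among those not called, IAA34, IAA20, IAA31 and IAA33 already lay there in the controls, between 2 and 3.68, which limits what a decrease can show. Of the 5 measured genes on the GH3 list 3 fell, and 3 fell when adjusted over the list alone. GH3.17 and GH3.9, which were not called, also lay near the low end in the controls (3.91 and 2.37). Of the 7 other early auxin genes 4 fell, and 6 when adjusted over the list alone. These included HAT2 (−2.11 ± 0.12), a homeodomain factor gene, and EXPA8 (−2.09 ± 0.14), an expansin gene. Also among them were LBD16 (−1.58 ± 0.23) and LBD29 (−1.27 ± 0.24), which act in lateral root initiation. LBD29 ended near the low end of the range. The camera adjusted p was 2.18e-09 for Aux/IAA, 9.36e-10 for GH3 and 2.73e-14 for the other early auxin genes, from the limma fit. With an estimated correlation the adjusted p was 0.00859 for each list, and fry gave 0.000799, 0.000176 and 6.33e-05. The median and the mean of each list were negative, as was the test.

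**Figure D1:**
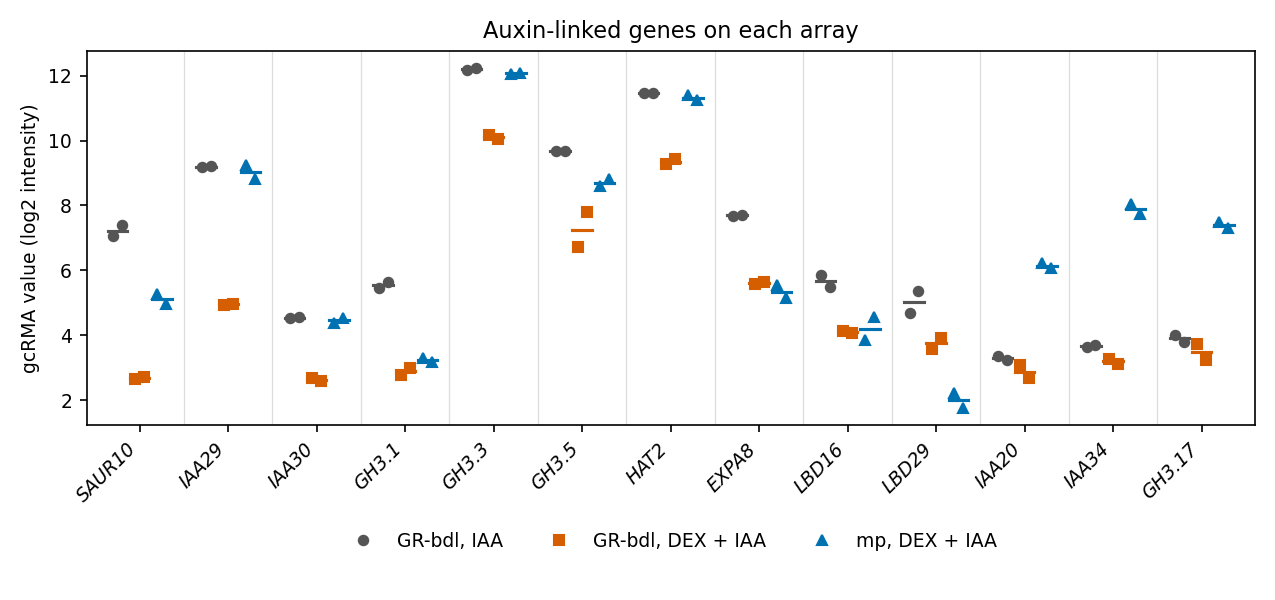
Each point is the gcRMA value (log2 intensity) of a named auxin-linked gene on 1 array, and the short lines are group means of 2 arrays. IAA29 stood at 9.20 in the controls, 4.96 in GR-bdl with DEX and 9.04 in mp, while IAA34 stood at 3.68 in the controls and 7.90 in mp.

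Some genes outside the tested auxin lists also changed after DEX. Family membership beyond the lists was not checked, so some of them may belong to early auxin families. Among the decreases were AT5G41400 (−3.58 ± 0.17), AT4G09890 (−3.57 ± 0.22), AT1G66940 (−3.12 ± 0.16), AT3G28420 (−2.72 ± 0.15) and AT5G12050 (−2.58 ± 0.14). AT4G09890 and AT3G28420 ended near the low end of the range. AT3G53250 rose by 1.94 ± 0.11 from near the low end of the range, with a limma adjusted p of 6.43e-05, and AT3G15570 rose by 1.61 ± 0.12. AT3G16560 and AT5G58570 rose by 1.47 and 1.24, and AT3G15720 rose from 2.93 ± 0.20 to 4.43 ± 0.40. AT2G20670 rose by 1.745 ± 0.347 (limma adjusted p = 0.0448). It was not called after a repeated quantile normalization (0.0577) or the filter on low means (0.0522). AT4G21310 rose by 1.11 ± 0.18 (limma adjusted p = 0.0206). With each array left out, these 2 rises ranged from 1.25 to 2.24 and from 0.854 to 1.362. ARR16, a cytokinin-induced type-A response regulator gene, rose by 1.73 ± 0.28. Its limma adjusted p was 0.0172, and 0.0645 and 0.104 without control array 1 and control array 2. WAG2, which encodes an AGC kinase linked to auxin transport, differed by −1.15 ± 0.21 and ZAT10, a stress-linked zinc finger gene, by −1.30 ± 0.18. The limma adjusted p of LBD16 was 0.00953, and 0.0577, 0.0653 and 0.0604 without DEX-treated array 1, DEX-treated array 2 and control array 1. That of LBD29 was 0.0378, and 0.148, 0.0989 and 0.195 without DEX-treated array 1, DEX-treated array 2 and control array 2. That of ZAT10 was 0.00924, and 0.0626 and 0.0648 without DEX-treated array 1 and control array 2. That of WAG2 was 0.0313, and 0.118, 0.186, 0.0601 and 0.0601 without control array 1, control array 2, mp array 1 and mp array 2. Among the 4 root genes, 4 photosynthesis genes, 3 shoot apex genes and 3 heat and cold genes measured, the smallest limma adjusted p was 0.0756 (JKD). Not called either were PHV of the vascular list, LHW and DOF5.8 of the MP-linked list, the clock gene GI (0.00 ± 0.11), the replication gene MCM7 and the reference genes SAND (−0.03 ± 0.13) and TIP41 (0.08 ± 0.12). Of the 34 added lists, 1 passed camera, and the smallest adjusted p with an estimated correlation was 0.844.

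In all, 145 probe sets were higher and 372 lower after DEX (limma, adjusted p under 0.05), 2.27% of those tested, and 28.1% of the calls were higher. With a change of at least 1 on the log2 scale, 33 were higher and 229 lower. Of the calls, 63 higher and 163 lower probe sets name a single gene. Over all probe sets the lowest difference was −5.93, against −4.54 for SAUR10. Leaving out control array 1 gave 50 higher and 225 lower, leaving out control array 2 gave 24 and 216, and leaving out DEX-treated array 2 gave 89 higher. DEX without the fusion protein was given to mp seedlings only, so its own effect in this line was not separated from that of the fusion protein.

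The second comparison set mp seedlings with DEX and IAA against GR-bdl seedlings with IAA alone. Of the 4 root genes of the preset list 3 fell in mp, and members of several wall-linked families fell further. The class III peroxidase genes AT4G26010 and AT4G30170 fell by 7.32 ± 0.15 and 7.22 ± 0.24 (SE, n = 2 per group) on the log2 scale, to near the low end of the range. EXPA7 and EXPA18, expansin genes of root hairs, fell by 3.80 ± 0.22 and 2.89 ± 0.25, and JKD, a gene of root radial patterning, fell by 1.52 ± 0.18. DFR, which encodes dihydroflavonol reductase of the anthocyanin pathway, rose by 6.70 ± 0.17, from 2.75 ± 0.08 to 9.45 ± 0.32 (SD, n = 2), with a limma adjusted p of 3.39e-08.

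Other genes at both ends of the ranking of probe sets paired with 1 gene lay near the low end of the range in 1 of the groups. Over all probe sets the highest difference was 9.53. AT4G17470 rose by 8.59 ± 0.12, AT2G47780 by 8.39 ± 0.15, AT1G48660 by 7.21 ± 0.14 and AT3G29970 by 6.75 ± 0.12. AT4G14090, AT1G72570 and AT1G17830 rose by 6.49, 6.01 and 5.91. AT2G25450, which encodes an oxygenase of glucosinolate formation, fell by 8.45 ± 0.11, to 2.56 ± 0.02, with a limma adjusted p of 1.03e-08. AT4G16260, SBT4.12, AT5G62340, AT4G26870 and AT4G38080 fell by 7.41, 7.27, 7.31, 7.26 and 7.17, of which SBT4.12 is a subtilase gene.

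The measured auxin genes moved in both directions in mp. Of the 7 Aux/IAA genes, IAA34 and IAA20 rose, by 4.22 ± 0.14 and 2.86 ± 0.15, and 5 were not called, with the same counts adjusted over the list alone. IAA29 differed by −0.16 ± 0.15 and IAA30 by −0.08 ± 0.12. Of the 5 measured genes on the GH3 list, GH3.17 rose by 3.49 ± 0.17, GH3.1 fell by 2.32 ± 0.13 and GH3.5 by 0.98 ± 0.30. The same held when adjusted over the list alone. GH3.3 differed by −0.14 ± 0.11. Of the 7 other early auxin genes 5 fell, by either adjustment: EXPA8 (−2.35 ± 0.14), LBD29 (−3.02 ± 0.24), LBD16 (−1.47 ± 0.23), XTH19 (−1.39 ± 0.11) and PUCHI (−0.44 ± 0.15). PUCHI lay near the low end of the range in both groups. HAT2 differed by −0.15 ± 0.12. SAUR10 fell from 7.22 ± 0.23 to 5.12 ± 0.23 (SD, n = 2). The other early auxin genes passed camera (limma adjusted p = 0.000444), with an adjusted p = 0.0893 with an estimated correlation. Aux/IAA and GH3 had a camera adjusted p of 0.272 each. Relative to the median of all probe sets (0.12), the Aux/IAA mean was 0.89 and the median −0.09, so they differed in sign. After the arrays were centred on the hybridization controls, IAA29 (−0.49), IAA30 (−0.42), IAA31 (−0.43), GH3.3 (−0.47) and HAT2 (−0.48) were called lower. That centring lowers every difference of this comparison by the same amount, so these calls are not particular to the genes. IAA31 lay near the low end of the range in both groups (2.34 in the controls and 2.25 in mp). GH3.5 lost its call without either control array or either mp array, with a limma adjusted p of 0.0695 to 0.135. PUCHI lost its call without any array other than control array 2, at 0.0573 to 0.322, and after median centring (0.0598).

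Single members of the remaining preset lists also differed in mp. ARR16 fell by 2.43 ± 0.28, COR15A, a cold-regulated gene, rose by 3.78 ± 0.18, and COR47 fell by 0.73 ± 0.13. HSP22, a heat-shock gene near the low end of the range in both groups, rose by 0.61 ± 0.11. It was not called after centring on the hybridization controls (0.27 on the log2 scale). GSTU25, a tau glutathione transferase gene, fell from 7.85 ± 0.26 to 4.55 ± 0.10, and YAB3, a leaf polarity gene, rose by 1.02 ± 0.14. PYK10, a root beta-glucosidase gene, differed by 0.10 ± 0.11. Of 4 photosynthesis genes, SBPASE of the Calvin cycle was called (0.31 ± 0.11), and PRK, RCA and LHCB4.1 were not (0.08, −0.18 and −0.17). SBPASE stood at −0.024 after centring on the hybridization controls, and lost its call without either control array or either mp array (limma adjusted p of 0.102 to 0.224) and after a repeated quantile normalization (0.0671). DOF5.8, placed downstream of MP by other work, differed by −0.52 ± 0.17, and lost its call without any array other than control array 2 (0.0576 to 0.292), after a repeated quantile normalization (0.0942) and after median centring (0.0537). LHW of the same list, PHV, GI, MCM7, SAND, TIP41, ARR15, PID2, WAG2 and ZAT10 were not called.

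Several families with roles in roots and cell walls were lower in mp. The families below were listed after the annotation had been seen, and members outside the naming rule were chosen after their values were seen. Of 55 class III peroxidase genes, 33 fell, 7 rose and 15 were not called, with a list mean of −2.15. Among those that rose was AT4G31760 (5.36 ± 0.16). Of 15 extensin genes, which encode wall glycoproteins, 9 fell and 1 rose, with AT3G28550 at −2.69 ± 0.22 and HRGP1 at −5.29 ± 0.21, the latter uncertain between copies. Of 11 genes on a wider root list, 6 fell, among them AT3G53980 (−6.89 ± 0.18), while NAI2 and JAL33 of the endoplasmic reticulum bodies rose by 0.67 and 1.03. Of 14 dirigent protein genes 7 fell, with AT4G13580 at −5.05 ± 0.26, and 2 rose. Of 10 xyloglucan endotransglucosylase genes 7 fell and 2 rose, including XTH33 (−1.73 ± 0.16) and XTH32 (2.37 ± 0.22). The camera adjusted p over 34 lists in the limma fit was 1.02e-12 for peroxidases, 0.000289 for extensins, 0.00544 for the root list, 0.0234 for dirigent proteins and 0.00923 for xyloglucan endotransglucosylases. With an estimated correlation the adjusted p was 0.51, 0.51, 0.51, 0.661 and 0.51, so none passed. The root list went from a camera p of 0.00064 to 0.0373 in that form though its estimated correlation was −0.00243. With 3 residual degrees of freedom, this form cannot decide whether correlation among genes accounts for the decreases. Of the 34 lists 7 passed camera and 26 passed fry, but with an estimated correlation the smallest adjusted p of all was 0.51. Relative to the median of all probe sets, the list means were −2.27, −1.71, −1.74, −1.24 and −0.74. Camera no longer passed the dirigent proteins (0.0561) and the xyloglucan endotransglucosylases (0.0718) after centring on the hybridization controls, though both means stayed negative. Restricted to probe sets with a mean above 4, it no longer passed the root list (0.0782) or the xyloglucan endotransglucosylases (0.138). Fewer genes were left by that filter, and the list means were then −3.62 for peroxidases, −3.71 for extensins, −1.77 for the root list, −2.42 for dirigent proteins and −0.47 for xyloglucan endotransglucosylases, so their size depends on it. Of 118 cytosolic ribosomal protein genes, 105 were not called.

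**Figure D2:**
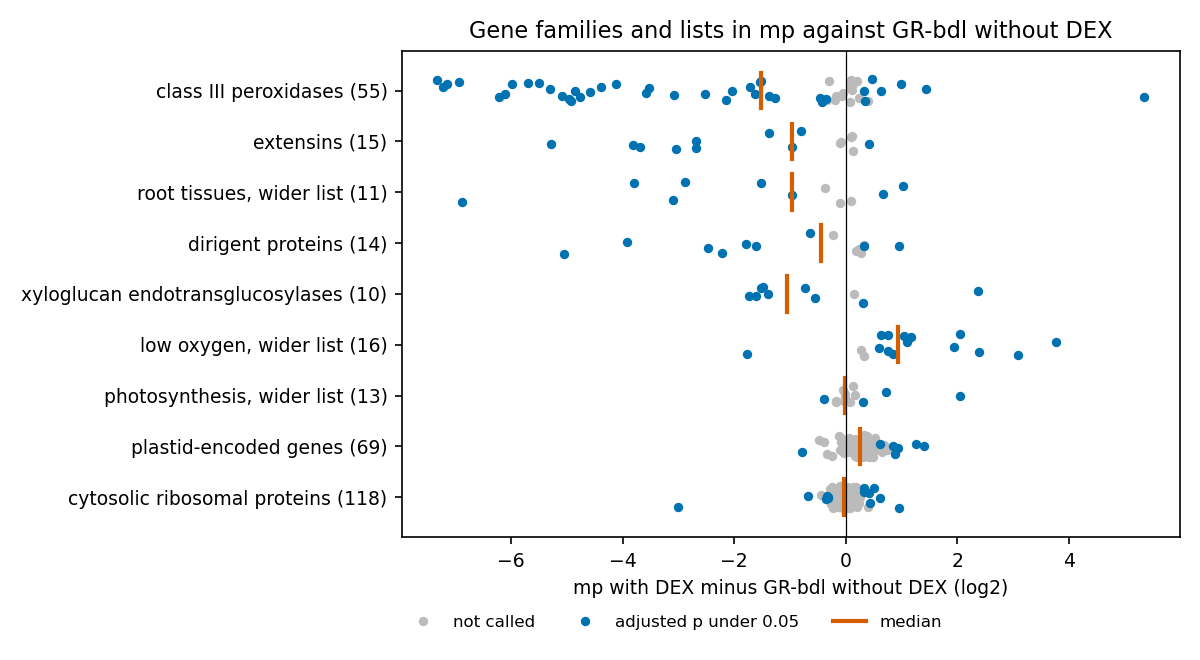
Each point is a gene, placed at its log2 difference between mp with DEX and GR-bdl without DEX, with 1 line per gene family or list and the number of genes in brackets. Blue points had a limma adjusted p under 0.05, and the orange bars are medians; 33 of 55 peroxidase genes were called lower, while the ribosomal protein genes lay mostly near 0.

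Altogether 5441 probe sets were higher and 3989 lower in mp than in the controls, 41.5% of those tested, and 1712 and 1784 changed by at least 1 on the log2 scale (limma). The higher share of the calls was 57.7%, but 25.7% after centring on the hybridization controls, which gave 2556 higher and 7383 lower and moved the median of all probe sets from 0.12 to −0.22. The hybridization controls themselves differed by a median of 0.33 between these groups, and the 24 poly-A controls, RNA added before labelling, by 0.61. Between GR-bdl with DEX and GR-bdl without DEX these medians were 0.05 and 0.365. The 3′ minus 5′ value of the ubiquitin control was 1.00 ± 0.20 in mp and 0.68 ± 0.004 in the controls (SD, n = 2). The actin and GAPDH controls went the other way, with 2.51 ± 0.05 and −0.74 ± 0.10 in mp against 2.66 ± 0.15 and −0.62 ± 0.006 in the controls. Line and DEX differed between these groups, and mp seedlings are known for failing to form an embryonic root. The accession background of each line is not given in the labels used here.

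The third comparison set mp against GR-bdl when both had received DEX and IAA. Some of the auxin genes that were low in DEX-treated GR-bdl seedlings were higher in mp. IAA29 was higher by 4.08 ± 0.15 (SE, n = 2 per group) and IAA30 by 1.82 ± 0.12, at limma adjusted p values of 2.19e-07 and 5.62e-06. GH3.3, HAT2 and SAUR10 were higher by 1.98 ± 0.11, 1.96 ± 0.12 and 2.44 ± 0.15. Others were not: GH3.1 (0.35 ± 0.13), EXPA8 (−0.26 ± 0.14) and LBD16 (0.11 ± 0.23) had limma adjusted p values of 0.0662, 0.192 and 0.746, and LBD29 was lower still. In DEX-treated GR-bdl and mp, GH3.1 (2.89 and 3.24) and LBD29 (3.75 and 2.00) lay near the low end of the range. GH3.1 was called higher after a repeated quantile normalization (0.0343), median centring (0.0486) or without DEX-treated array 2 (0.0468). EXPA8 was called lower after centring on the hybridization controls (−0.53) or without mp array 1 (0.0338). GH3.9, near the low end of the range, was also called lower after that centring (−0.52, limma adjusted p = 0.0154). IAA34 and IAA20, which had differed from the controls too, were higher by 4.69 ± 0.14 and 3.27 ± 0.15, and GH3.17, at 7.40 ± 0.13 (SD) in mp, was also higher (limma adjusted p = 7.46e-07). ARR16 differed by −4.16 ± 0.28 and was called lower.

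Of the 7 Aux/IAA genes 5 were higher in mp, and 5 when adjusted over the list alone. The 5 include IAA18 (0.60 ± 0.19), which lost its call without DEX-treated array 2 (limma adjusted p = 0.209), control array 1 (0.0546), control array 2 (0.0546) or mp array 1 (0.217), and under the hybridization centring (0.148). Of the 5 measured genes on the GH3 list 3 were higher, with GH3.5 at 1.44 ± 0.30, and 4 when adjusted over the list alone. Of the 7 other early auxin genes, HAT2 was higher, LBD29 (−1.75 ± 0.24) and XTH19 (−0.98 ± 0.11) were lower and 4 were not called, with the same counts adjusted over the list alone. The camera adjusted p was 0.00131 for Aux/IAA and 0.0256 for GH3 in the limma fit. With an estimated correlation these were an adjusted p of 0.109 and 0.14, so neither passed in that form. The other early auxin genes had 0.458, and their fry direction was upward (adjusted p = 0.558) where the mean (−0.11) and camera were downward.

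Outside the auxin lists, most of the largest differences among probe sets paired with 1 gene were in genes named in the second comparison. AT2G47780, AT4G17470, DFR and AT5G44440 were higher in mp by 8.79, 8.65, 6.67 and 6.10. AT2G25450, AT4G16260, SBT4.12, AT3G01190 and AT5G40590 differed by −8.66, −7.50, −7.39, −7.29 and −7.19. Of the peroxidase genes 31 were lower and 5 higher (camera adjusted p = 9.79e-13, limma fit), and with an estimated correlation the adjusted p was 0.604. Of the 34 added lists 10 passed camera and 22 passed fry, but with an estimated correlation the smallest adjusted p was 0.604, so none passed in that form. EXPA7 (−3.29 ± 0.22) and EXPA18 (−2.98 ± 0.25) were lower, as was JKD (−0.72 ± 0.18), which lost its call without DEX-treated array 2 (limma adjusted p = 0.085) or mp array 2 (0.0652). YAB3 was higher by 0.84 ± 0.14, COR15A by 3.48 ± 0.18 and ZAT10 by 1.60 ± 0.18. WAG2 (0.70 ± 0.21) lost its call without DEX-treated array 1 (0.0931), mp array 1 (0.13) or mp array 2 (0.0682), and under the hybridization centring (0.113). COR47 differed by −0.91 ± 0.13 and GSTU25 by −2.91 ± 0.15. In all, 5031 probe sets were higher and 4083 lower in mp (limma), with 1735 and 1735 changed by at least 1. The higher share was 55.2%, and 29.7% after centring on the hybridization controls (2848 higher and 6736 lower).

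The last comparison asked which transcripts differed from the controls in the same direction after DEX in GR-bdl and in mp. SAUR10 was lower in both, at 2.68 ± 0.04 after DEX and 5.12 ± 0.23 in mp against 7.22 ± 0.23 in the controls. GH3.1 and AT4G09890 were lower in both, with DEX differences of −2.67 and −3.57 and mp differences of −2.32 and −1.46. AT3G42800 (−2.21 and −3.02), AT1G02660 (−1.54 and −3.61), AT3G19200 (−1.94 and −2.66) and AT1G06830 (−1.60 and −2.92) were also lower in both. BAT1, an acyltransferase gene linked to brassinosteroids, stood at 5.03 ± 0.32 after DEX and 3.23 ± 0.39 in mp against 6.72 ± 0.42 in the controls, and its call after DEX was lost without DEX-treated array 1 (limma adjusted p = 0.0747) or control array 2 (0.068). AT3G15570 was higher in both, by 1.61 ± 0.12 and 2.07 ± 0.12. The other 7 of the 8 highest genes lost their call after DEX when some array was left out.

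Of the 372 probe sets lower after DEX, 201 (54.0%) were also lower in mp, against 65.2 for independent lists of these sizes, 85.2 for lists matched on mean level, and at most 0 in 100 simulations of unchanged groups with shared controls. Of the 145 higher probe sets, 77 (53.1%) were also higher in mp, against 34.7, 44.4 and at most 1. The simulations left out all real effects and gave almost no shared calls, so they set no bound on what the shared controls add. Opposite calls numbered 72, lower after DEX and higher in mp (89.0 for independent lists and 110.6 for matched ones), and 33 for the reverse (25.4 and 34.2). The covariance of the differences was 0.0489, against 0.0101 in the simulations, a difference of 0.0388. Their correlation was 0.16, against 0.50 in the simulations; effects in mp alone lower a correlation but not a covariance, so these correlations do not measure a shared effect. Both comparisons used the same 2 control arrays, and part of the excess may come from them. Lower in both were 119 without control array 1 and 112 without control array 2, and 313 after centring on the hybridization controls. Higher in both were 41, 44, 28, 13 and 51 without DEX-treated array 1, DEX-treated array 2, control array 1, control array 2 and mp array 2.

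**Figure D3:**
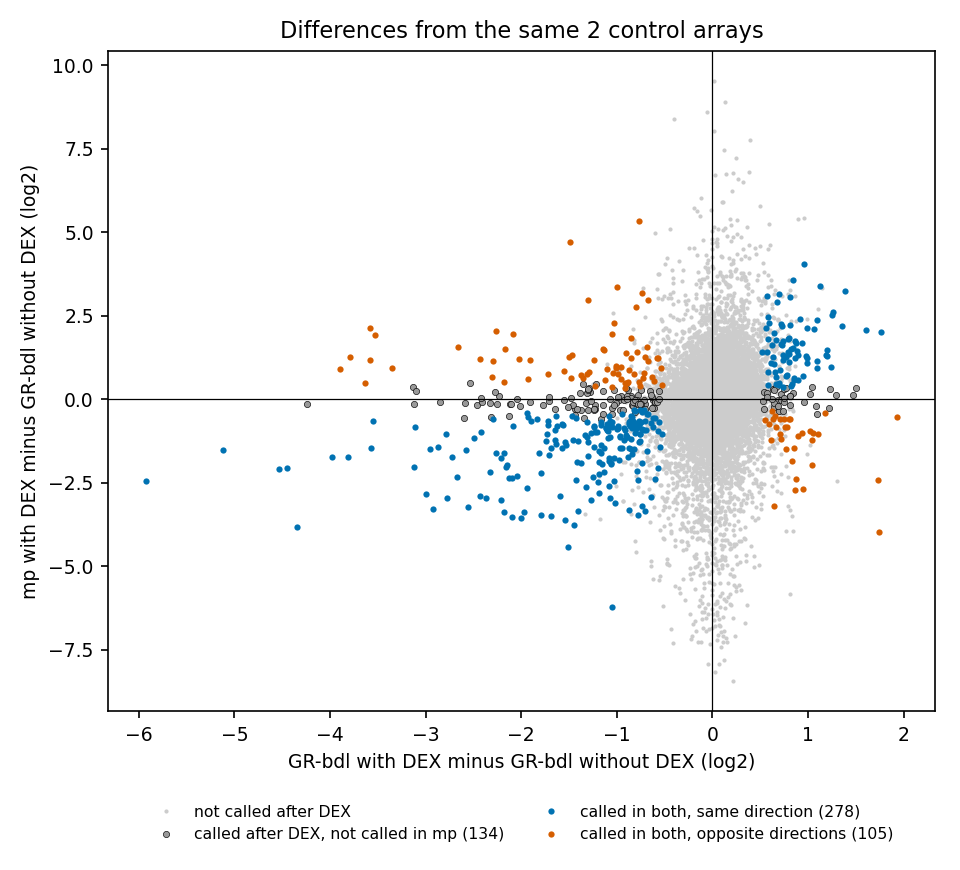
Each point is a probe set, with the log2 difference between GR-bdl with and without DEX on the horizontal axis and that between mp and GR-bdl without DEX on the vertical axis. The points called in both include 201 that were lower in both and 77 that were higher in both, and the mp axis spans −8.45 to 9.53.

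Of the 372 probe sets lower after DEX, 222 (59.7%, exact 95% interval 54.5 to 64.7, which treats probe sets as independent) were higher in mp than in DEX-treated GR-bdl, IAA29, HAT2 and GH3.3 among them. Another 63 (16.9%) were lower. Their median difference was −1.14 after DEX, −0.57 in mp against the controls and 0.65 in mp against DEX-treated GR-bdl. Of all probe sets, 22.1% were higher in this last comparison. That share is not a like baseline, because the 372 were chosen for low values on the same DEX-treated GR-bdl arrays.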

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

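The comparison of these shares with all probe sets was chosen only after the results were seen; the other tests in this part were set before.

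The control probe set for 25S ribosomal RNA, which enters no comparison of the report, was higher in both mp arrays than in both control arrays, with a log2 difference of means of 2.97. Its intensities were 172 and 45.4 in mp, 17.0 and 7.51 in the controls, and 19.3 and 10.2 in GR-bdl with DEX. Its probes are uncertain between copies, and the difference was not tested.

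Among the 372 probe sets lower after DEX in GR-bdl, which include SAUR10, IAA29 and GH3.3, DEX itself could be the cause, since the only other DEX-treated line was mp. If it were the whole cause, the DEX-treated mp arrays would show the same drop. Instead 59.68% of these probe sets were higher in mp than in DEX-treated GR-bdl, with a median difference of 0.65. The set was chosen for low values on the same DEX-treated GR-bdl arrays, which pushes both figures up by an amount not tested. Within that limit the figures argue against DEX alone, unless a change in mp offset the drop gene by gene. No mp array without DEX was used here, so that offset was not tested. Repression of auxin response by the released GR-bdl protein stays open as a hypothesis.

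For the 201 probe sets lower both after DEX and in mp, chance in the shared control arrays may add to the overlap; simulated groups gave at most 0 shared calls, but they leave out every real effect, so that test, set beforehand, was wrong for this question and how much the controls add stays open. DEX, which both groups received and the controls did not, is a second possible cause. Between the DEX-treated groups, 57.71% of these probe sets differed, above the bound of 50% set beforehand, but that bound was wrong, since 40.1% of all probe sets differed between the same groups. The share higher in mp was 26.4% (exact 95% interval 20.4 to 33.0), which includes the 22.1% of all probe sets, and the set was chosen partly on the mp arrays. DEX, a loss of auxin response through MP and other differences of the mp line cannot be told apart for these probe sets. No control array received DEX, and the mp arrays differ from the controls in line as well.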

How the results depend on the processing

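Centring on the hybridization controls, median centring for the list tests and all settings of the added lists were chosen only after the data were seen; the other alternatives were planned.

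Across the alternatives, the counts of calls kept within 1.5 times of the reported values except as follows. With a change of at least 1 on the log2 scale, 33 were higher and 229 lower after DEX, 1712 and 1784 in mp against the controls, 1735 and 1735 in mp against GR-bdl with DEX, and 13 higher and 91 lower in both, fewer by construction. Centring on the hybridization controls gave 2556 and 7383, 2848 and 6736 for the mp comparisons and 313 lower in both. These controls were higher in mp, by medians of 0.33 and 0.25 in the 2 mp comparisons. Centring on them therefore lowers every difference of a comparison by the same amount. Why the controls differed was not tested. Leaving out each array gave 24 to 105 higher and 216 to 332 lower after DEX, where a group left with a single array was assumed to vary like the others. The lowest of both came without control array 2 (24 and 216), with 50 and 225 without control array 1 and 89 higher without DEX-treated array 2. Likewise 13 to 55 were higher in both (41, 44, 28, 13 and 51 without DEX-treated array 1, DEX-treated array 2, control array 1, control array 2 and mp array 2) and 112 to 182 lower in both (119 and 112 without control array 1 and control array 2). The covariance was 0.0466 after a repeated quantile normalization, 0.0593 for means above 4, and 0.0410 to 0.0678 with each array left out; the cause was not tested.

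For means above 4, Aux/IAA and GH3 kept too few genes to be tested. The other early auxin genes were the 1 list left, which passed after DEX and in mp against the controls, and 0 passed in mp against GR-bdl with DEX (camera adjusted p = 0.998), where this list had not passed before (0.458). In mp against the controls 0 passed with an estimated correlation and 2 with fry, against 1 by camera. In mp against GR-bdl with DEX 0 passed with an estimated correlation, against 2 by camera and 2 by fry. SBPASE in mp turned to −0.024 on the hybridization controls, through the shift common to all probe sets. The mean of the plastid-encoded genes after DEX, −0.19, turned to 0.14 without DEX-treated array 2, and was −0.524 without DEX-treated array 1, the ends of its range. The cause of the change of sign in the plastid-encoded genes was not tested.

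The shared replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at −0.03, −0.04 and 0.10. With the replicate block, 161 were higher and 398 lower after DEX, 5308 and 3968 in mp against the controls, 5000 and 4045 in mp against GR-bdl with DEX, and 90 and 218 in both. PUCHI (limma adjusted p = 0.0548) and SBPASE (0.0666) in mp against the controls, and AT5G59350 after DEX (0.0512), were not called with the block.

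Of the named genes called, 22 of 37 after DEX, 47 of 52 and 35 of 38 in the mp comparisons kept their call wherever they were tested among 14 alternatives. Genes removed by the filter on low means, such as IAA30 and GH3.1, were not tested there and could still count as kept. Values under 4, 43.1 to 44.1% of an array, limit what a decrease can show.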

Other observations

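The lists in this part were written after the annotation had been seen and before any difference had been, and their alternatives and the members named here were chosen only after the data were seen; the test of the photosynthesis list was set before its result.

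Genes known to rise when oxygen is low were higher in mp than in the controls. Of 16 measured genes on a wider list, 13 rose and 1 fell, with a mean of 1.19 on the log2 scale (camera adjusted p = 0.00136, limma fit). With an estimated correlation the adjusted p was 0.756, where the estimate was 0.726. AT5G10040 rose by 3.77 ± 0.45 (SE, n = 2 per group), AT2G17850 by 3.09 ± 0.31, CML38, a calmodulin-like gene, by 2.40 ± 0.21 and PDC2, a pyruvate decarboxylase gene, by 0.85 ± 0.12, while AT1G19530 fell by 1.78 ± 0.18. After DEX in GR-bdl their mean was 0.10 (camera adjusted p = 0.745). Against GR-bdl with DEX, 13 were again higher in mp and 1 lower, with a mean of 1.08 (camera adjusted p = 0.0016, and adjusted p = 0.814 with an estimated correlation).

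Some peptide and organelle genes also differed in mp. Of 11 RALF-like peptide genes, 4 were lower in mp than in GR-bdl with DEX, including RALFL32 (−2.34) and RALFL22 (−2.01). Camera gave an adjusted p of 0.0226 (limma fit), 0.0533 without DEX-treated array 2, 0.0653 for probe sets with a mean above 4, and the adjusted p was 0.604 with an estimated correlation. In the same comparison 16 of 69 plastid-encoded genes were higher, close to the share of 22.1% over all probe sets. Their mean was 0.45 (camera adjusted p = 0.00622). The mean was 0.12 without DEX-treated array 2 (adjusted p = 0.693), the adjusted p was 0.0563 without mp array 1, and it was 0.867 with an estimated correlation. Of 16 mitochondrion-encoded genes 8 were higher, with a mean of 0.54 (camera adjusted p = 0.0409; adjusted p = 0.796 with an estimated correlation). Their camera adjusted p was 0.131, 0.0544 and 0.115 without DEX-treated array 2, mp array 1 and mp array 2, and 0.0696 for probe sets with a mean above 4. After DEX in GR-bdl, the mean of the plastid-encoded genes, −0.19, passed camera (adjusted p = 3.17e-06; adjusted p = 0.844 with an estimated correlation) but was −0.524 without DEX-treated array 1 and 0.14 without DEX-treated array 2.

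The root and wall families lower in mp passed camera, but none passed with an estimated correlation (smallest adjusted p of 0.51). Their lower levels could reflect a smaller share of root tissue, as mp seedlings are known to lack the embryonic root. A loss of MP-dependent expression within tissues is another candidate. A smaller root share alone would lower root genes alike and raise genes of green tissue alike. Of the 11 genes on the wider root list 6 fell, with a list mean of −1.62, and 2 rose, NAI2 and JAL33 (0.67 and 1.03). PYK10 was not called (0.10 ± 0.11, limma adjusted p = 0.47, 13.19 in the controls and 13.30 in mp). PYK10, NAI2 and JAL33 are not limited to roots and were picked out after their values were seen, so they do not decide the question. The median of 13 photosynthesis genes was −0.00859, below 0 where their mean was 0.20, and 3 rose (LHCB4.3 by 2.06, AT1G56190 by 0.72 and SBPASE by 0.31) while PSAN fell by 0.38. After centring on the hybridization controls SBPASE stood at −0.024, so this median near 0 over members that went both ways decides nothing. The candidates, and an accession difference between the lines, cannot be told apart here, because all of them go with the mp line. For DEX alone the values argue against it. With DEX in both groups, 31 of 55 peroxidase genes were lower in mp and 5 higher, with a mean of −2.22. The extensin, root, dirigent and xyloglucan endotransglucosylase means were −1.52, −1.56, −1.27 and −0.60. After DEX in GR-bdl, each of these lists had 0 calls, with a peroxidase mean of 0.06.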
